A study of Mus musculus with 10 samples.

How the data were processed

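Poly(A) RNA of activated mouse CD8+ T cells was sequenced in 10 libraries, 5 WT and 5 GS KO. The values used were the gene counts deposited by the authors, whole numbers per Ensembl gene that were not normalized. STAR, featureCounts, DESeq2 and the mm10 build are named in the submitters' processing notes. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here, so counts of close paralogs, processed copies and overlapping or antisense genes are uncertain. The count table held 32285 genes. Symbols and coordinates came from GENCODE M21 on GRCm38, the assembly of mm10, which matched 32235 genes, and the 50 others held 0.0316% of counts. Groups and replicate numbers came from the sample titles, and all 10 columns were matched to samples by name.

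Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr given the group (minimum count 10), which left 13384 genes, libraries were scaled by TMM, and the robust quasi-likelihood test compared GS KO with WT with no covariate. P-values were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05. A log2 fold change is GS KO minus WT, its SE is the fold change divided by the square root of the F statistic, and CPM values are scaled by TMM. On counts simulated for this comparison over 13384 genes, 65% of genes changed by 1.5 fold and 82% of genes changed by 2 fold were recovered, with 6 false calls. With no change simulated, 0 genes were called. The simulation changed 200 genes, far fewer than were called in the data, and drew each gene independently. Its rates may therefore not hold for the data. The libraries held from 66430466 to 84539578 counts, so the spread between libraries and not counting error set the precision of most genes.

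Before the data were examined, 42 gene lists were fixed, and 38 had the 5 tested members needed for a list test. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 38 lists. Of these, 17 were called, 15 lower and 2 higher. With an estimated correlation 0 were called at the adjusted threshold (lowest adjusted p = 0.0547), and fry called 20. Values per library, marker levels and shares of counts were compared by two-sided exact permutation tests and adjusted over 14 measures. Of the 819 list genes tested, 83 rose and 286 fell.

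The genes named are Glul, the 12 largest rises and the 12 largest falls, up to 4 members of each list with the smallest p, and fixed genes that included Asns, Slc1a5, Myc, Gzmb, Ifng, Tcf7, Pdcd1 and Il2ra. The largest rises and falls were taken among genes past the threshold with a mean of at least 1 CPM, all 5 GS KO libraries on one side of the WT mean, and a symbol that is not a predicted model. From a list in which no member passed, up to 2 were given as values. This rule gave 156 genes, of which some are not reported here. Genes outside it are said to have been chosen after their values were seen.

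The alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, no count filter, a filter of 1 CPM in 5 libraries, limma-voom with quality weights, the replicate number as a block, 1 surrogate variable from sva 3.50.0, a log2 fold change of 1, glmTreat against 0.25, and leaving out each library in turn. For the list tests they also included fry, an estimated correlation and lists without shared members. Removal of a trend with transcript length and GC content in each library was added after the data were examined. Length was that of all annotated exons of a gene joined, and GC content was that of its longest transcript. A planned covariate for mouse sex was not run, because it was meant for libraries of both sexes, and in all 10 libraries Xist was at 1450 to 2270 CPM and Ddx3y at 0 CPM. Counts of the 20 pairs of libraries within a group were compared by chi-square, which was 16.6 to 181.3 per degree of freedom, so no pair was a repeat of one library.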

Results

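Gene expression was measured by poly(A) RNA sequencing in 10 libraries of mouse CD8+ T cells, the cytotoxic arm of the T cell compartment, to compare cells with and without glutamine synthetase. Glul encodes this enzyme, which makes glutamine from glutamate and ammonia. The 5 WT libraries came from mice with floxed Glul and no CD4-Cre, and the 5 GS KO libraries from mice that carried CD4-Cre, a recombinase active in T cells. Presence of CD4-Cre and loss of Glul went together in these libraries, so their effects cannot be told apart. CD8+ T cells isolated from spleens were stimulated for 48 h on plates coated with anti-CD3 and anti-CD28, then kept for 3 days with IL-2, in medium with 0.6 mM glutamine, and were taken at day 5. WT replicates 1 to 5 held 68030145, 68720462, 66430466, 75180758 and 74473980 gene counts, and GS KO replicates 1 to 5 held 77168598, 77738763, 72700519, 84539578 and 71467873. The labels do not say which animals or cultures the replicates came from, so p-values measure only the spread between these samples, which may be technical.

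Glul (mm10 chromosome 1, 153899944 to 153909723, plus strand) was lower in all 5 GS KO libraries than in any WT library. Its level was 52.5 ± 3.36 CPM (SD, n = 5) in WT and 0.717 ± 0.310 CPM (SD, n = 5) in GS KO. The log2 fold change was −6.18 ± 0.26 (SE), with an adjusted p = 1.112e-06 in edgeR's quasi-likelihood test. The count covers the whole gene, so it can include reads from exons outside the deleted part. Of the 5 tested neighbours of Glul, 1 fell and 1 rose. Rgs8 fell (log2 fold change −1.42, adjusted p = 0.00523). The counts adjusted over the list alone were the same, and as a list these neighbours were not called (median −0.06, and −0.13 to −0.01 over left-out libraries, camera adjusted p = 0.808). None rose without GS KO replicate 5, 2 rose with limma-voom, and 3 fell with DESeq2 or no count filter.

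**Figure D1:**
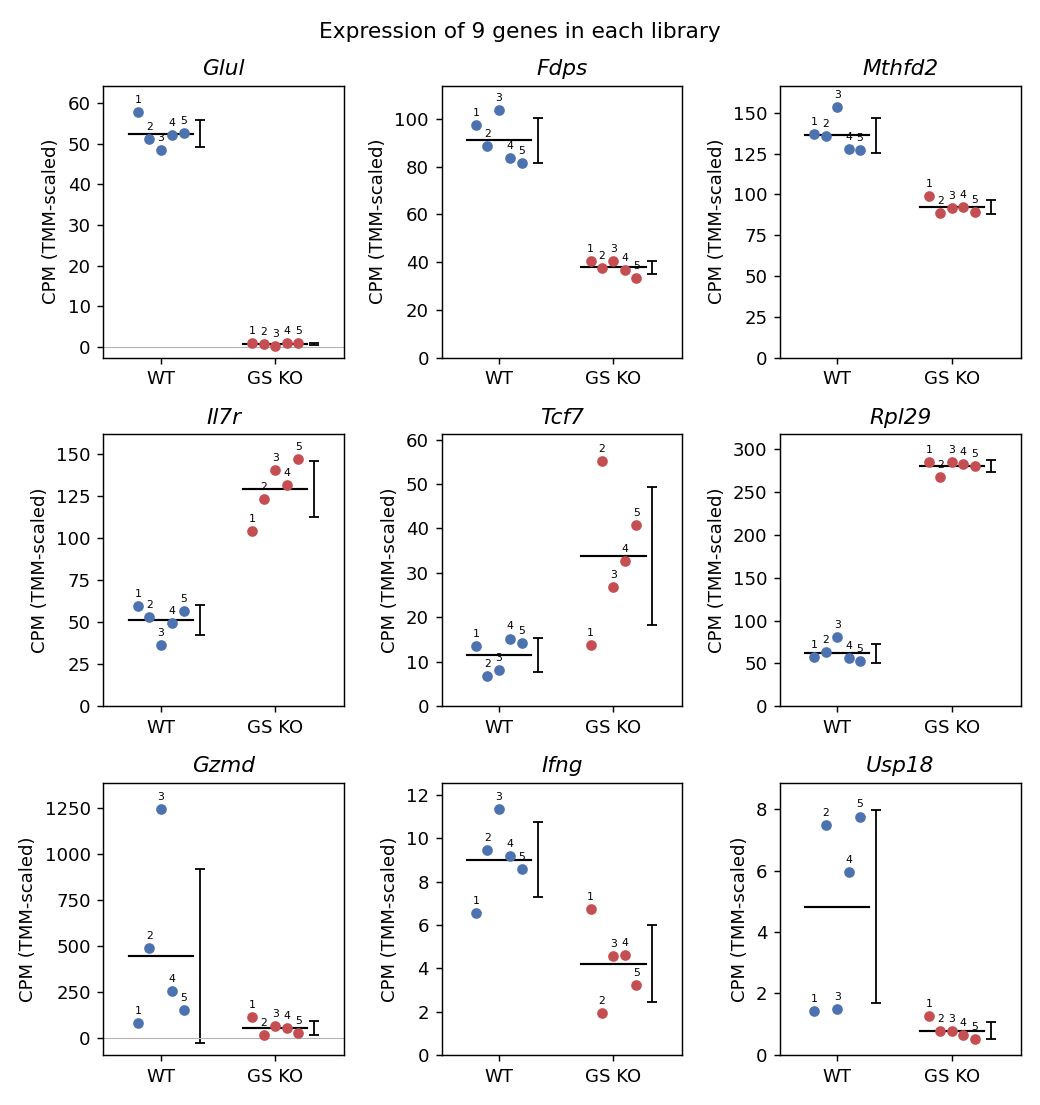
Expression of 9 genes as TMM-scaled CPM (vertical axes, linear and starting at or below 0) in the 5 WT and 5 GS KO libraries, each point a library with its replicate number, the horizontal line the group mean and the bar 1 SD. Glul lay near 52.5 CPM in WT and below 1 CPM in GS KO, whereas Gzmd and Usp18 varied widely among the WT libraries.

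GS KO cells differed from WT cells in many genes, mostly by small amounts. Of 13384 genes tested, 4355 (32.5%) changed at an adjusted p below 0.05, of which 2096 rose and 2259 fell in GS KO. The median absolute log2 fold change of the changed genes was 0.33, and 152 rose and 190 fell by a log2 fold change of 1 or more. Without GS KO replicate 5, 3280 genes changed and 1378 rose. With limma-voom, 3152 rose.

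Sterol and fatty acid synthesis genes were lower in GS KO. Of 24 tested genes of cholesterol synthesis and its SREBP2 programme, 21 fell (23 adjusted over the list alone) and none rose. Fdps, which makes farnesyl diphosphate, went from 91.1 ± 9.43 CPM in WT to 37.7 ± 2.92 CPM in GS KO (SD, n = 5; log2 fold change −1.27 ± 0.08 SE, adjusted p = 1.03e-05). Idi1, the isomerase before it, fell by 0.98 on the log2 scale, and Cyp51, a sterol demethylase, by 0.78. The list had a median log2 fold change of −0.42 and was called by camera with a preset correlation of 0.01 (adjusted p = 1.26e-12), but not with an estimated correlation (adjusted p = 0.154). Of 16 fatty acid synthesis genes, 9 fell (11 adjusted over the list alone) and none rose. Fads2, a desaturase, fell by 1.59, Scd1, which makes monounsaturated fatty acids, by 0.96, and Acaca, which makes malonyl-CoA, by 0.68 on the log2 scale. Slc25a1, the mitochondrial citrate carrier, fell by 0.61. The median was −0.32 (camera adjusted p = 3.55e-05), and the adjusted p = 0.0547 with an estimated correlation.

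Genes for amino acid, one-carbon and nucleotide synthesis were also lower. Of 17 serine and one-carbon genes, 12 fell (13 adjusted over the list alone) and none rose, with a median of −0.46. Psat1 and Phgdh, enzymes of serine synthesis, fell by 0.53 and 0.49 on the log2 scale, and Mthfd2, a mitochondrial folate enzyme, fell from 136 ± 10.8 to 92.3 ± 4.21 CPM (SD, n = 5). The camera adjusted p = 6.73e-06, and the adjusted p = 0.154 with an estimated correlation. Among 36 genes of the amino acid response governed by ATF4, 17 fell (20 adjusted over the list alone) and 1 rose (3 over the list alone), with a median of −0.28. Yars, a tyrosyl-tRNA synthetase, and Aldh18a1, of proline synthesis, fell by 0.54 and 0.46. Asns, which makes asparagine using glutamine, fell by 0.51 (adjusted p = 0.000512). The gene that rose was Ddit4, an inhibitor of mTORC1 (0.50, adjusted p = 0.00659). The list was called (camera adjusted p = 6.73e-06; adjusted p = 0.154 with an estimated correlation). Without the genes shared with other lists its median was −0.18 (adjusted p = 0.0122). The number that rose was 3 without WT replicate 1, 4 with limma-voom, and 2 without WT replicate 2, with upper-quartile scaling, with the stricter filter or with the length and GC trend removed.

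In pyrimidine synthesis, 13 of 16 genes fell and 1 rose (the same counts adjusted over the list alone). Tk1, the cytosolic thymidine kinase, fell from 90.4 ± 4.77 to 52.6 ± 2.05 CPM (SD, n = 5; log2 fold change −0.78 ± 0.05 SE), and Dctpp1, Nme1 and Dut, which act on nucleotides, fell by 0.54, 0.56 and 0.35. The median was −0.35 (camera adjusted p = 2.85e-06; adjusted p = 0.154 with an estimated correlation). In purine synthesis, 11 of 15 genes fell (12 adjusted over the list alone) and none rose. Adsl, Gart and Impdh2 fell by 0.38, 0.32 and 0.38. The median was −0.25 (camera adjusted p = 4.07e-05; adjusted p = 0.253 with an estimated correlation). Of 18 genes that use or make glutamine and glutamate, Glul not among them, 8 fell (9 adjusted over the list alone) and 2 rose. Their median was −0.20 (camera adjusted p = 0.00272; adjusted p = 0.154 with an estimated correlation), and the call was lost when genes shared with other lists were removed (median −0.11, adjusted p = 0.243). In that list 1 gene rose without WT replicates 4 or 5 or GS KO replicates 3, 4 or 5. Slc1a5, a glutamine transporter, was at 411 ± 92.1 and 344 ± 112 CPM (SD, n = 5; adjusted p = 0.431). Of 17 amino acid transporters, 3 rose and 3 fell (3 and 4 adjusted over the list alone; median −0.10, camera adjusted p = 0.513). The median was −0.16 without WT replicate 3 and −0.18 with the length and GC trend removed, and the test pointed up without genes shared with other lists (adjusted p = 0.975). Slc38a9, a lysosomal arginine sensor, rose by 0.71 and Slc38a2 by 0.31, whereas Slc1a4 and Slc7a5 fell by 0.97 and 0.49. Without WT replicate 3, 5 transporters fell, as with 1 surrogate variable, and 6 fell with limma-voom.

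Lists of ribosome biogenesis and MYC-linked genes, ribosomal protein genes and nuclear genes of oxidative phosphorylation were called as lower. They held many members that did not pass. Of 30 ribosome biogenesis and MYC-linked genes, 23 fell (26 adjusted over the list alone) and none rose. Npm1 and Ncl, abundant nucleolar proteins, fell by 0.54 and 0.49 on the log2 scale, and Srm, a spermidine synthase, by 0.68. The median was −0.32 (camera adjusted p = 1.37e-09; adjusted p = 0.344 with an estimated correlation). Myc, in the same list, was at 295 ± 38.4 CPM in WT and 325 ± 20.1 CPM in GS KO (SD, n = 5; adjusted p = 0.218), but passed as higher without WT replicate 1 (0.21, adjusted p = 0.032). Among 81 ribosomal protein genes, 42 fell (47 adjusted over the list alone) and 2 rose. Rpl27 fell by 0.42, and the genes that rose were Rpl29 and Rpl34. The median was −0.25 (camera adjusted p = 1.46e-08; adjusted p = 0.589 with an estimated correlation), and fry, a test of the list by itself, gave an adjusted p = 0.0731. The number that fell was 27 without WT replicate 2, and 25 without GS KO replicate 2 or without GS KO replicate 4. Of 42 nuclear genes of oxidative phosphorylation, 26 fell (30 adjusted over the list alone) and none rose. Cycs, cytochrome c, fell by 0.46, and Cyc1, Ndufs8 and Atp5c1, subunits of complexes III, I and V, fell by 0.31, 0.32 and 0.25. The median was −0.22 (camera adjusted p = 2.83e-09; adjusted p = 0.348 with an estimated correlation).

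A trend of expression with transcript length moved with these groups. Length was that of all annotated exons of a gene joined, and genes with a mean above 2 log2 CPM were used. Across these genes within a library, Spearman's rho of centred expression on length was −0.157 ± 0.157 in WT and 0.233 ± 0.0371 in GS KO (SD, n = 5; two-sided exact permutation p = 0.0079, the smallest these splits can give, adjusted p = 0.0556 over 14 measures). Genes are not independent replicates. With a length and GC trend removed in each library, a setting chosen after the data were examined, the median of the oxidative phosphorylation genes was −0.12 and 18 fell, and that of the ribosomal protein genes was −0.13 and 26 fell. Both remained called by camera (adjusted p = 1.24e-05 and 2.77e-05). Ribosomal protein genes took 4.68 ± 0.473% of counts in WT and 4.20 ± 0.111% in GS KO (SD, n = 5; exact permutation p = 0.0159, adjusted p = 0.0556), and the share was 5.49% in WT replicate 3.

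Of 22 citric acid cycle genes, 11 fell (12 adjusted over the list alone) and none rose. Pcx, which makes oxaloacetate from pyruvate, fell from 37.3 ± 5.47 to 15.9 ± 3.03 CPM (SD, n = 5; log2 fold change −1.23 ± 0.14 SE), and Fh1, Suclg1 and Idh3a fell by 0.40, 0.43 and 0.38. The median was −0.19 (camera adjusted p = 0.000142; adjusted p = 0.154 with an estimated correlation). Among 24 genes of the unfolded protein response, 16 fell (18 adjusted over the list alone) and 1 rose. The chaperones Hspa5 and Calr fell by 0.58 and 0.52, and Sdf2l1 by 0.67. The gene that rose was Ern1, a sensor of unfolded protein (0.47), named after its values were seen. In that list 2 genes rose without WT replicate 1, without WT replicate 3 or with limma-voom, and 3 with 1 surrogate variable. The median was −0.26 (camera adjusted p = 2.31e-05; adjusted p = 0.206 with an estimated correlation). Among 23 redox genes linked to NRF2, 9 fell (10 adjusted over the list alone) and 1 rose (median −0.16, camera adjusted p = 0.00276; adjusted p = 0.154 with an estimated correlation). Tkt and G6pdx, of the pentose phosphate pathway, fell by 0.58 and 0.28, and Gclm, of glutathione synthesis, by 0.42. No gene of that list rose when any library except WT replicate 4 was left out, nor with RLE scaling, no count filter or limma-voom, and 2 rose without WT replicate 4 or with the length and GC trend removed. Of 23 glycolysis entries, 7 fell (8 adjusted over the list alone) and 2 rose, with a median of −0.23 (camera adjusted p = 0.036; adjusted p = 0.669 with an estimated correlation). Pkm, Eno3 and Slc16a1, a lactate carrier, fell by 0.41, 0.69 and 0.50. This call was lost without WT replicate 1 (median −0.12, adjusted p = 0.293), WT replicate 3 (−0.20, 0.0581), GS KO replicate 1 (−0.26, 0.0568) or GS KO replicate 3 (−0.26, 0.0511), with fry (0.0871), and without the genes shared with other lists (−0.20, 0.0768). The 23 entries stand for 22 symbols. The number that rose was 1 when any library except WT replicate 1 or GS KO replicate 3 was left out, with no count filter, and with the length and GC trend removed.

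**Figure D2:**
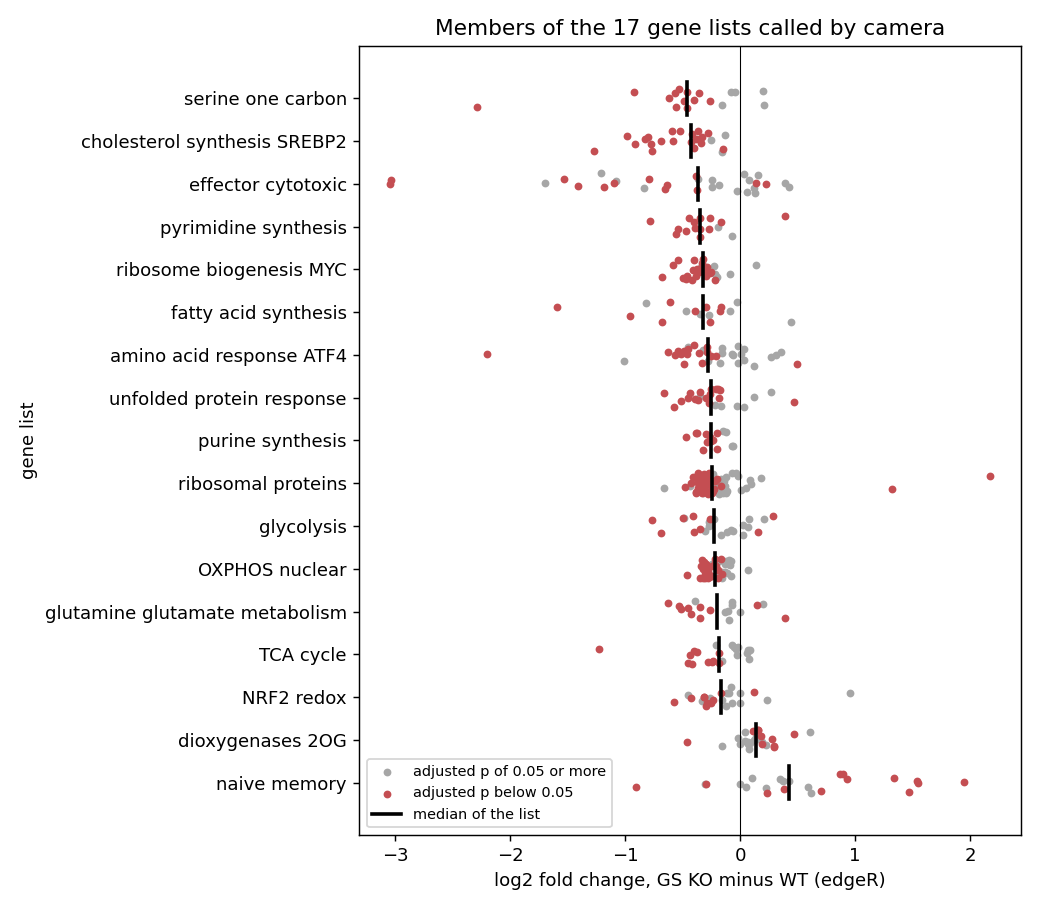
Log2 fold change of GS KO against WT (horizontal axis) for each tested member of the 17 gene lists called by camera with a preset correlation (vertical axis), each point a gene, red at an edgeR adjusted p below 0.05, with the list median as a black bar. Medians ran from −0.46 for serine and one-carbon genes to 0.43 for naive and memory genes, and Rpl29 and Rpl34 stood apart from the other ribosomal protein genes.

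Genes typical of naive and memory T cells were higher in GS KO. Of 23 tested, 11 rose (13 adjusted over the list alone) and 2 fell, with a median of 0.43 (camera adjusted p = 0.000648; adjusted p = 0.154 with an estimated correlation). Il7r, the interleukin-7 receptor, rose from 51.0 ± 8.94 to 129 ± 16.5 CPM, Bach2, a repressor of effector genes, from 18.9 ± 3.48 to 55.0 ± 6.92 CPM, and S1pr1, the receptor for lymph node exit, from 3.63 ± 1.47 to 14.1 ± 3.55 CPM (SD, n = 5 each). Tcf7, a transcription factor of memory cells, was at 11.5 ± 3.86 CPM in WT and 33.9 ± 15.5 CPM in GS KO (SD, n = 5; log2 fold change 1.55 ± 0.36 SE, adjusted p = 0.00964). Its level in GS KO replicate 1 was 13.7 CPM, within the WT range. The genes that fell were Eomes, a T-box factor (−0.91), and Myb (−0.30), the latter chosen after its values were seen. Cxcr3, a chemokine receptor, rose by 1.47. The mean of this list (centred log2 CPM) was 0.036 in GS KO replicate 1, 0.291 to 0.463 in the other GS KO libraries and −0.495 to −0.20 in WT. The mean log2 CPM of CD4 and regulatory T cell markers was also higher in GS KO (0.0230 ± 0.176 in WT and 0.503 ± 0.0838 in GS KO, SD, n = 5; exact permutation p = 0.0079, the smallest these splits can give, adjusted p = 0.0556).

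Effector and cytotoxic genes were lower as a list, with a less stable call. Of 30 tested, 11 fell (12 adjusted over the list alone) and 2 rose (3 over the list alone), with a median of −0.37 (camera adjusted p = 0.0331; adjusted p = 0.61 with an estimated correlation). Ifng, interferon gamma, was at 9.01 ± 1.74 CPM in WT and 4.21 ± 1.79 CPM in GS KO (SD, n = 5; log2 fold change −1.10 ± 0.28 SE, adjusted p = 0.0133). Gzmb, the main granzyme, fell by 0.38 (adjusted p = 0.0143) from 19420 ± 190.2 CPM, but did not pass with the length and GC trend removed (−0.25, adjusted p = 0.0725). Its level was 18950 CPM in GS KO replicate 1 and 12420 to 15460 CPM in the other GS KO libraries. Nkg7, needed for granule release, fell by 0.66, and Runx3, a CD8 lineage factor, rose by 0.22. The list call was lost without WT replicate 2 (adjusted p = 0.0602), WT replicate 3 (0.0588), GS KO replicate 2 (0.117) or GS KO replicate 5 (0.055, with 7 genes that fell), with a stricter filter (0.119), with fry (0.0804), and with the length and GC trend removed (0.0793), with medians from −0.37 to −0.30 in these settings. The mean of this list (centred log2 CPM) was 0.15 in GS KO replicate 1, within the WT range of −0.054 to 0.682, and −0.84 to −0.145 in the other GS KO libraries. Without GS KO replicate 1 the median was −0.48 (adjusted p = 0.00726). The number that rose was 1 without WT replicates 4 or 5 or GS KO replicates 2, 4 or 5, and 4 with limma-voom, 1 surrogate variable or the length and GC trend removed. The largest falls after Glul included the granzyme genes Gzme (−3.05), Gzmd (−3.04) and Gzmg (−2.93), neighbours on chromosome 14. Gzmd was at 81.7, 488, 1244, 254 and 149 CPM in WT replicates 1 to 5, and at 115, 16.5, 63.1, 52.2 and 23.6 CPM in GS KO. Without WT replicate 3 the log2 fold changes were −2.23 for Gzme, −2.17 for Gzmd and −2.19 for Gzmg, and Gzmg no longer passed (adjusted p = 0.0509). Gzmg also did not pass without GS KO replicate 4 (−2.87, adjusted p = 0.0519) or with no count filter (−2.92, 0.0514). These genes are close paralogs whose counts depend on how shared reads were assigned.

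Receptor genes of activated and inhibited T cells moved both ways. Among 22 inhibitory receptor and exhaustion genes, 7 fell (8 adjusted over the list alone) and 5 rose, with no call (median −0.37, and −0.19 with the stricter filter, camera adjusted p = 0.432). Cd160 and Cd244a fell by 1.26 and 1.58 and Cd38, an NAD-degrading enzyme, by 1.57, whereas Cd101 rose by 1.17. Without GS KO replicate 3, or without GS KO replicate 4, 3 genes rose, and with no count filter 4 rose and 4 fell. Pdcd1, which encodes PD-1, was at 18.4 ± 2.84 and 19.4 ± 4.82 CPM (SD, n = 5; log2 fold change 0.08, adjusted p = 0.754), and its log2 fold change was −0.08 without GS KO replicate 1. Among 27 genes of T cell receptor activation, 7 fell (8 adjusted over the list alone) and 5 rose, with no call (median −0.04, and −0.10 to 0.01 over left-out libraries, camera adjusted p = 0.73). The test pointed up with fry (adjusted p = 0.97) and without genes shared with other lists (0.919). The costimulatory receptors Icos and Tnfrsf18 rose by 0.88 and 0.75, and Batf3 fell by 1.15. Il2ra, the high-affinity IL-2 receptor chain, was at 1271 ± 42.5 and 1290 ± 86.5 CPM (SD, n = 5; log2 fold change 0.02, adjusted p = 0.796), with a log2 fold change of −0.03 without GS KO replicate 1 and −0.01 with the length and GC trend removed. Of 25 dioxygenases that depend on 2-oxoglutarate, 9 rose and 1 fell (the same counts adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.00276; adjusted p = 0.206 with an estimated correlation). The histone demethylases Phf8, Kdm5a and Kdm7a rose by 0.29, 0.28 and 0.47. With the length and GC trend removed this list was not called (median 0.08, adjusted p = 0.129) and 5 genes rose, the same number as without GS KO replicate 4, and Kdm5a did not pass (0.15, adjusted p = 0.0504). With limma-voom 14 rose.

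Interferon response genes differed among the WT libraries. Of 41 tested, 10 fell and 2 rose (the same counts adjusted over the list alone), with a median of −0.55 and no call (camera adjusted p = 0.151). Usp18, which dampens interferon signalling, was at 1.43, 7.50, 1.49, 5.95 and 7.77 CPM in WT replicates 1 to 5 and between 0.518 and 1.27 CPM in GS KO (log2 fold change −2.61 ± 0.53 SE, adjusted p = 0.00426). Oas2, an antiviral enzyme, was at 0.713, 4.60, 0.691, 5.22 and 7.03 CPM in WT (−2.30, adjusted p = 0.017). It was between 0.600 and 1.00 CPM in GS KO, a range that held WT replicates 1 and 3. Bst2 fell by 0.66, whereas Gbp2, a guanylate-binding protein, and Socs1, a signalling inhibitor, rose by 1.27 and 0.47. The list was called as lower without WT replicate 1 (median −0.72, adjusted p = 0.00172, 19 genes fell) and without WT replicate 3 (median −0.66, adjusted p = 0.0157, 16 fell), both with the preset correlation. Over all libraries the adjusted p = 0.912 with an estimated correlation. Between 4 and 6 genes fell without WT replicate 2, WT replicate 4, WT replicate 5, GS KO replicate 2, GS KO replicate 3, GS KO replicate 4 or GS KO replicate 5, 5 with no count filter, and 26 with limma-voom. The median was −0.31 without WT replicate 2 and −0.30 with the stricter filter. Oas2 has close paralogs whose counts depend on how shared reads were assigned.

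The largest rises were in genes of low to moderate level. Insrr, an insulin receptor-related kinase (chromosome 3, 87796951 to 87816101), was at 0.0891 ± 0.0864 CPM in WT and 2.56 ± 0.234 CPM in GS KO, and Tmem108 (chromosome 9, 103482947 to 103761837) at 0.132 ± 0.119 and 2.48 ± 1.49 CPM (SD, n = 5 each). Rpl29 (chromosome 9, 106429454 to 106431568) rose from 61.97 ± 10.96 to 280.5 ± 7.17 CPM (SD, n = 5; log2 fold change 2.18 ± 0.10 SE, adjusted p = 1.112e-06), and Mcub, a subunit of the mitochondrial calcium channel (chromosome 3, 129914960 to 129970206), by 2.57. Rpl34 (chromosome 3, 130726831 to 130730398) was at 43.6 CPM in GS KO replicate 1, in the WT range of 36.5 to 48.5 CPM, and between 112 and 123 CPM in the other GS KO libraries. Rpl29 and Rpl34 have processed copies in the genome, so their counts depend on how shared reads were assigned. Usp35, Amt and Igf1r rose by 1.70, 1.70 and 1.48. Among the falls, Spp1, which encodes osteopontin, went from 742 ± 665 to 115 ± 46.5 CPM (SD, n = 5), with a log2 fold change of −2.69 that was −2.04 without WT replicate 3. Mcpt8, a granule protease, fell by 2.99, or by 1.99 without WT replicate 3. Scin, Chn2, Syt12 and Car2, a carbonic anhydrase, fell by 2.75, 2.84, 2.78 and 2.67.

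T cell genes were abundant, and markers of other blood cells lay at very different levels. The 13 CD8 T cell markers had a mean log2 CPM of 8.37 ± 0.0366 in WT and 8.33 ± 0.0481 in GS KO (SD, n = 5; exact permutation p = 0.198). Of these, 3 fell and 2 rose, the same counts adjusted over the list alone (median −0.03, and −0.08 to −0.002 over left-out libraries, camera adjusted p = 0.473). Thy1 and Lat fell by 0.36 and 0.39 and Cd2 rose by 0.43. In that list 1 rose without WT replicates 2, 4 or 5 or GS KO replicates 1, 2, 4 or 5. Of the CD4 and regulatory T cell markers, Cd4 itself was at 0.767 CPM in WT and 1.97 CPM in GS KO, Foxp3 at 0.545 and 0.573 CPM, and Zbtb7b, a CD4 lineage factor, rose by 0.36. Of the 6 tested, 2 rose and none fell, the same counts adjusted over the list alone (median 0.495, camera adjusted p = 0.103). Among other markers, chosen after their values were seen, Lyz2 of myeloid cells was at 0.0370 and 0.0106 CPM and Clec9a of dendritic cells at 0.0057 and 0.0102 CPM in WT and GS KO, whereas Cd68 of myeloid cells was at 7.00 and 5.76 CPM. Of the B cell list, H2-Ab1 was at 5.69 and 5.26 CPM (15.9 CPM in WT replicate 1), Cd79b at 2.24 and 2.77 CPM and Cd74 at 1.72 and 1.56 CPM, also chosen after their values were seen. Of 6 tested B cell markers none rose or fell, also adjusted over the list alone (median 0.10, and −0.01 to 0.45 over left-out libraries, camera adjusted p = 0.513). Ighm, at 41.2 and 61.4 CPM, passed as higher with DESeq2 (0.57, adjusted p = 0.032) and without GS KO replicate 1 (0.70, adjusted p = 0.0318), and Ighd, at 0.254 and 0.473 CPM, with DESeq2 (0.90, adjusted p = 0.0443), limma-voom (0.97, adjusted p = 0.0139), the length and GC trend removed (1.01, adjusted p = 0.0393) and without WT replicate 1 (1.16, adjusted p = 0.0231). The γδ T cell genes Trdc and Tcrg-C2 were at 15.3 and 72.8 CPM in WT and 15.8 and 52.5 CPM in GS KO, and none of the 5 tested members rose or fell, also adjusted over the list alone. That list was not called (median 0.04, mean −0.03 and a test pointing down, camera adjusted p = 0.892). Its median was −0.18 to 0.13 over left-out libraries, and the test pointed up without WT replicate 4 or GS KO replicate 3, with fry, and with the length and GC trend removed. Tcrg-C2 passed as lower with DESeq2 (−0.48, adjusted p = 0.0368) and limma-voom (−0.76, adjusted p = 0.0112). The myeloid, dendritic, erythroid and sex-linked lists had 3, 4, 4 and 2 tested members, too few for a list test. Of the 4 dendritic markers 3 fell, Bst2 (85.5 to 54.1 CPM), Batf3 (15.1 to 6.80 CPM) and Itgax (1.23 to 0.490 CPM), of which Bst2 and Batf3 also stand in the interferon and activation lists. Of the erythroid and platelet markers Itga2b rose (3.17 to 5.77 CPM), and of the myeloid markers Ccr2, which T cells also express, rose (336 to 440 CPM). No myeloid marker rose without WT replicates 1 or 5 or GS KO replicates 1, 3, 4 or 5, or with the length and GC trend removed, and 1 fell without WT replicate 1. Itgax, Itga2b and Ccr2 were chosen after their values were seen. No sex-linked gene rose or fell, although 1 rose without WT replicate 1, with limma-voom and with 1 surrogate variable.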

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

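The tests of linked alleles, of copies of Rpl29 and Rpl34 and of the ratio of Mcpt8 to Cpa3, and the removal of the length and GC trend, were chosen after the results were seen. Of 402 groups of 5 libraries scored, 31 held a library set apart from the other 4 by a Dixon ratio. Chance gives about 1 in 20. The ratio weighs a gap against the range of the 5 libraries, so a flagged gap can be small. For Rpl29, GS KO replicate 2 was at 8.07 log2 CPM and the other GS KO libraries at 8.13 to 8.16.

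Among list means (centred log2 CPM), WT replicate 3 lay apart in oxidative phosphorylation (0.303), homing receptors (−0.575), γδ T cell markers (−0.654) and type 2 and type 17 cytokine genes (−1.31). Ribosomal proteins took 5.49% of its counts against 4.31 to 4.64% in the other WT libraries. WT replicate 1 lay apart in dioxygenases (0.0999), fatty acid oxidation (−0.0704), glutamine and glutamate genes (0.173) and ribosome biogenesis and MYC-linked genes (0.405). WT replicate 2 lay apart in B cell markers (−0.601) and GS KO replicate 2 in NK-like receptors (−0.76).

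Among single genes, in log2 CPM, WT replicate 3 stood apart in Cdt1 (5.93), Cxcr3 (2.93), Slc25a20 (4.83), Cd2 (7.12), Tcrg-C4 (1.68) and Rpl31 (4.82). WT replicate 1 stood apart in Cd160 (4.98), Bid (5.35), Sesn1 (4.77) and Impdh2 (5.57). GS KO replicate 1 stood apart in S1pr1 (3.02), Plscr4 (−1.23), Cyc1 (6.9), Eomes (6.9), Adsl (6.7) and Rpl34 (5.45). GS KO replicate 2 stood apart in Rpl29 (8.07) and Hsp90aa1 (10.2), and GS KO replicate 5 in Cyp51 (5.75) and Cd244a (2.68).

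The 15 lists called lower were mostly metabolic or biosynthetic, with effector genes among them. Fatty acid oxidation, hexosamine and amino acid transporter genes were not called as lists. The trend of expression with transcript length differed between the groups. With a length and GC trend removed, 14 of the 15 lists called lower remained lower, which argues against that trend as the whole cause, although the falls of oxidative phosphorylation and ribosomal protein genes became smaller. Without WT replicate 3, 13 of the 15 remained lower, which argues against that library alone. Part of the size of these falls may still come from the length trend, and 0 lists were called with an estimated correlation. An effect of genotype stays open as a hypothesis.

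Insrr, Tmem108, Mcub, Rpl29 and Rpl34 rose in steps, and Tmem108 (0.321 CPM), Mcub (1.41 CPM) and Rpl34 (43.6 CPM) were lowest in GS KO replicate 1 among the GS KO libraries. Alleles of a different strain background carried near these genes are a candidate explanation. Of 296 tested genes within 5 Mb, 8 (2.7%) changed by a log2 fold change of 1 or more, against 2.56% of all tested genes. That lay at percentile 61.3 of 10000 random sets, which decides neither way. The genes named above were themselves left out of that count. It therefore did not assess that Mcub lies near Rpl34 on chromosome 3, and Tmem108 near Rpl29 on chromosome 9. Reads shared with processed copies could not be examined, since 0 entries named as copies of Rpl29 or Rpl34 were found among the genes of the count table. Genotype and background cannot be told apart here, because the labels give no strain.

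Mcpt8, Fcer1g and Tyrobp fell, with Kit (−2.05, adjusted p = 0.0318), which was chosen after its values were seen, and without WT replicate 3 their log2 fold changes were −1.99, −1.43, −0.98 and −1.19 (Kit adjusted p = 0.0594). Tyrobp (−1.87) did not pass without GS KO replicate 2 (−1.86, adjusted p = 0.0621), GS KO replicate 3 (−1.83, 0.0642) or GS KO replicate 4 (−1.78, 0.0717). Basophils or mast cells in the WT libraries are a candidate source, and the highest WT mean among Cpa3, Fcer1a, Ms4a2 and Hdc was 0.992 CPM (Cpa3), between the bounds set for and against it. The ratio of Mcpt8 to Cpa3 differed 25.5 times across WT libraries (0.748 to 19.1), with at least 29 counts of Cpa3 in each. That spread met the bound set against those cells as the source of Mcpt8. Cpa3 lay near the floor (0.44 to 1.85 CPM), however, so no conclusion is drawn from this ratio alone. The ratio of Gzmd, a neighbouring granzyme gene, to Mcpt8 was 82.8 to 107 in the WT libraries, a spread of 1.3 times. Mcpt8 itself ran from 0.789 to 15 CPM there, with at least 52 counts. Mcpt8 thus followed a gene of the effector list, which argues against basophils or mast cells as its main source. No bound had been set for that ratio. It covers Mcpt8 only, and such cells stay open as a source of Kit, Fcer1g and Tyrobp.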

How the results depend on the processing

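The length and GC setting was chosen after the data were examined. The count of genes changed in GS_KO against WT was 4355, and 3760 with the replicate block (1800 rose, 1960 fell), 3594 of them shared. The numbers are not used as pairs: same-numbered libraries correlated at −0.041 to 0.08 and no sample correlated best with its own number. The count was 4978 with DESeq2, 4353 with RLE, 4442 with upper-quartile scaling, 3891 with no filter, 4267 with the stricter filter, 6211 with limma-voom (3152 rose), 5659 with 1 surrogate variable and 4474 with the length and GC trend removed (3651 shared). Leaving out a library gave 3280 to 4976 changed, 1378 to 2497 that rose and 1900 to 2479 that fell. With a log2 fold change of at least 1, 342 changed (152 rose, 190 fell), and with glmTreat against 0.25, 873 (405 rose, 468 fell), as stricter thresholds give fewer. Other causes were not tested. Glul in GS_KO against WT stayed lower in every setting run (−6.38 to −5.98, highest adjusted p = 0.000388).

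List tests called 17 lists, 16 to 18 without a library, and 0 with an estimated correlation. Of 147 named genes past the threshold, 129 passed in each of the up to 19 settings at that threshold that gave a value (the stricter thresholds not among them) and 18 did not in at least one, 9 of them under the replicate block (Gzmd, Gzme, Gzmg, Mcpt8, Oas2, Tyrobp, Cx3cr1, Trac and Casp8, adjusted p from 0.0521 to 0.082), where 7 effector genes fell, and 4 interferon genes rose and 2 fell. The block lost no list call and added that of heat shock genes (adjusted p = 0.0442). Direction turned for Tcrg-C4 with limma-voom (−0.02), for Pdcd1 over left-out libraries (−0.076 to 0.167), and for Il2ra over left-out libraries (−0.034 to 0.036) and with the length trend removed (−0.012). None of these passed the threshold in the main test, and the cause was not tested. The sex covariate was not run, its condition being unmet. Depth limits genes of low level most, and some named genes, such as Tyrobp, had group means below 1 CPM.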

Other observations

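The removal of the length and GC trend was chosen after the data were examined. Lysosome and homing genes moved both ways. Of 34 autophagy and lysosome genes, 11 rose (13 adjusted over the list alone) and 7 fell, with a median of 0.14 and no call (camera adjusted p = 0.0603). Ctsl, a lysosomal protease, rose from 1.86 to 4.73 CPM, whereas Neu1, a sialidase, fell by 0.42 on the log2 scale. The list was called as higher without WT replicate 3 (median 0.15, adjusted p = 0.00598, 17 rose), with the length trend removed (0.12, adjusted p = 0.0428) and with fry (0.0112), while 6 rose without WT replicate 4 or GS KO replicate 5. Over all libraries the adjusted p = 0.43 with an estimated correlation. With limma-voom or 1 surrogate variable 19 rose. Of 21 homing receptors, 7 rose and 3 fell (8 and 4 adjusted over the list alone; median 0.29, camera adjusted p = 0.278). The median was 0.02 (adjusted p = 0.829) without the genes shared with other lists and 0.18 without WT replicate 3. Cx3cr1, a chemokine receptor, fell by 0.79. Without WT replicate 5, 4 rose, and without GS KO replicate 3, GS KO replicate 4 or GS KO replicate 5, 3 rose. The number that fell was 1 without WT replicates 2, 3 or 5 or GS KO replicates 1 or 5. By fry the homing list (adjusted p = 0.0256), fatty acid oxidation (0.0311), hexosamine genes (0.00114), heat shock genes (0.00408) and CD4 markers (0.000726) moved on balance one way. With an estimated correlation camera gave an adjusted p = 0.531 for homing, an adjusted p = 0.669 for fatty acid oxidation, an adjusted p = 0.253 for hexosamine genes, an adjusted p = 0.309 for heat shock genes and an adjusted p = 0.253 for CD4 markers. Of 18 fatty acid oxidation genes, 5 rose and 2 fell, also adjusted over the list alone (median 0.06, and 0.03 to 0.07 over left-out libraries, camera adjusted p = 0.356). Cpt1a, which carries fatty acids toward mitochondria, rose by 0.61, and Etfb, an electron carrier, fell by 0.41. With the length trend removed 1 fell. Of 8 hexosamine genes, 5 fell and 1 rose, also adjusted over the list alone (median −0.20, camera adjusted p = 0.113). Ogt, which attaches O-GlcNAc to proteins, rose by 0.49, and 2 rose in that list with limma-voom or 1 surrogate variable.

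Among 23 immediate early and heat shock genes, 5 fell and 3 rose (6 and 4 adjusted over the list alone), with a median of −0.31 (camera adjusted p = 0.0586). Hspd1 and Hspe1, mitochondrial chaperones, fell by 0.60 and 0.58, and Fosl2 rose by 0.77. It was called as lower without WT replicate 5 (median −0.34, adjusted p = 0.0481), and its median was −0.18 without WT replicate 1, while over all libraries the adjusted p = 0.309 with an estimated correlation. In that list 1 rose without WT replicates 2, 4 or 5 or GS KO replicates 2, 4 or 5, and 8 fell with limma-voom or 1 surrogate variable. Of 30 mitosis genes 2 fell, Ube2c by 0.61 and Cdk1 by 0.37 (0 adjusted over the list alone; median −0.23, camera adjusted p = 0.113). That list was called as lower without WT replicate 2 (median −0.30, adjusted p = 0.0243) or WT replicate 3 (−0.34, 0.0011) with the preset correlation, whereas over all libraries the adjusted p = 0.912 with an estimated correlation. Without WT replicate 3, 7 fell, with limma-voom 9 and with 1 surrogate variable 18, and without any one of WT replicates 1, 4 and 5 or GS KO replicates 1 to 5, 1 fell. The median was −0.11 without WT replicate 1. Cdk1 did not pass without any one of WT replicates 1, 4 and 5 or GS KO replicates 1 to 5 (−0.40 to −0.27, adjusted p from 0.0557 to 0.0735), nor with no count filter (−0.37, 0.0599). Of 30 replication genes 4 rose and 2 fell (3 and 1 adjusted over the list alone; median 0.01, camera adjusted p = 0.787). The median was −0.05 to 0.04 over left-out libraries, and the test pointed down without WT replicate 3. Ccne1, a cyclin, fell by 0.56. Without WT replicate 3, with limma-voom and with 1 surrogate variable 6 fell, and 1 fell without WT replicates 1, 2, 4 or 5 or GS KO replicates 1, 2, 3 or 4. In that list 2 rose without WT replicate 2 or WT replicate 4 and 1 without GS KO replicate 3, GS KO replicate 4 or GS KO replicate 5. Of 22 hypoxia genes 3 rose and 2 fell (2 and 2 adjusted over the list alone; median −0.02, camera adjusted p = 0.993). The median was −0.09 to 0.05 over left-out libraries, and the test pointed up without WT replicates 1 or 3 or GS KO replicates 1, 2 or 5, with fry, with the stricter filter and with the length trend removed. Mif, a cytokine, fell by 0.67, while Bnip3l, a mitophagy receptor, rose by 0.52. Without WT replicate 1, 6 rose, and with limma-voom 9. Of 25 p53 and apoptosis genes 3 fell and 1 rose, also adjusted over the list alone (median −0.01, mean 0.004, test down, camera adjusted p = 0.773). The median was −0.11 to 0.12 over left-out libraries, and the test pointed up without WT replicate 3 and with the length trend removed. Aen, a nuclease, fell by 0.22. Without WT replicate 3, 7 rose and 3 fell, with limma-voom 7 and 7, with 1 surrogate variable 7 and 4, with DESeq2 or upper-quartile scaling 3 and 3, and without WT replicate 1, 1 and 5. None rose without WT replicates 2 or 4 or GS KO replicates 2, 3, 4 or 5. Of 17 NK-like receptor genes 2 fell (1 adjusted over the list alone; median −0.29, camera adjusted p = 0.73), with 1 that fell without GS KO replicates 2, 3 or 4 and 4 with DESeq2. With limma-voom 2 rose, and without GS KO replicate 2, 1 rose. The median was −0.14 without WT replicate 1, −0.15 without WT replicate 2, −0.08 without WT replicate 3, −0.19 without GS KO replicate 5, and −0.16 without GS KO replicate 2, where the test pointed up (adjusted p = 0.866). Of 14 type 2 and type 17 genes 1 rose and 1 fell (1 and 0 adjusted over the list alone; median 0.33, camera adjusted p = 0.465), with Rora higher by 0.69. The median was 0.11 without WT replicate 3, 0.07 without GS KO replicate 1 and 0.20 without genes shared with other lists. In that list 3 rose without GS KO replicate 2 or with DESeq2, and 2 without WT replicates 1 or 3, with limma-voom or with 1 surrogate variable. None fell without WT replicates 2, 4 or 5 or GS KO replicates 2, 4 or 5, and 2 fell with DESeq2, limma-voom, 1 surrogate variable or the length trend removed. Of 13 genes of the mitochondrial genome 1 rose, also adjusted over the list alone, mt-Nd5 by 0.21 (median −0.01, and −0.04 to 0.04 over left-out libraries, mean 0.02, test up but down without WT replicate 2, camera adjusted p = 0.73), and the list was called as higher with the length trend removed (0.11, adjusted p = 0.0128, 3 rose), while over all libraries the adjusted p = 0.958 with an estimated correlation. Without GS KO replicate 4, 3 rose, and without WT replicate 1, with limma-voom or with upper-quartile scaling, 2 rose.

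Ahcy, which clears S-adenosylhomocysteine, was chosen after its values were seen. Its log2 fold change was −2.29 (adjusted p = 0.0464), with levels from 11.9 to 178 CPM in WT and from 8.41 to 55.3 CPM in GS KO.

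Of 100 drawn splits of the libraries into groups of 5, 1 gave as many changed genes, the genotype split itself (4355). The highest of the others gave 3, which argues against chance division of these libraries as the source of that count. Each of the others mixed the genotypes, so any other difference between the groups would give the same result.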
